A study of Mus musculus with 10 samples.

How the data were processed

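Poly(A) RNA of 10 samples was measured, each a library of reporter-positive cells of the 3xR mouse embryonic stem cell line at day 14. Groups were taken from the sample titles: Col2a1-eGFP+ cells in DMSO (4 libraries), Prg4-tdTomato+ cells in DMSO (3 libraries) and Prg4-tdTomato+ cells in Fsk (3 libraries). The authors deposited a single table of raw read counts per gene, with 56748 genes in rows and the 10 libraries in columns named as in the labels. The unit was checked on the values, which are whole numbers with totals from 15355459 to 20408696. Per the labels, RNA was extracted with Trizol, and per the submitters' processing notes the genome build was mm10. The aligner, the counting program, the annotation and the use of strand are not given in the sources used here, so genes that overlap or share reads with near-identical copies are uncertain. Of the table's gene identifiers, 52125 (91.9%) are in GENCODE M21, from which the printed GRCm38 coordinates were taken by identifier.

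Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the group as its argument, which left 16169 genes, and libraries were scaled by TMM. Negative binomial dispersions were estimated and a quasi-likelihood model (glmQLFit, robust) with group as its only term was fitted to all 10 libraries, so that the 3 groups share 1 estimate of the spread with 7 residual degrees of freedom. Each comparison was tested with glmQLFTest and p-values were adjusted by Benjamini-Hochberg at 0.05. The standard error of a log2 fold change is its size divided by the square root of the F statistic. Levels are edgeR's CPM on TMM-scaled library sizes. The reporter genes were also tested by an exact two-sided permutation test of log2 CPM, which ignores the replicate numbers.

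Gene lists were fixed from general knowledge before the data were examined, as were the design, the rule for named genes and most alternatives. The 27 lists were chondrocyte, hypertrophic cartilage and osteoblast, joint and superficial zone, tendon, fibrous matrix, AP-1 and NFI factors, cAMP and CREB targets, hedgehog targets, WNT targets, BMP targets, TGF-beta targets, cell cycle, matrix proteinases, skeletal muscle, cardiac muscle, smooth muscle, neural, endothelial, blood, pluripotency, epithelial and endoderm, adipocyte, dissociation and heat shock, unfolded protein and amino acid stress, hypoxia and glycolysis, interferon response, and mitochondrially encoded genes. Lists with at least 5 tested members were tested by camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01. Estimated correlations and fry were run beside it. The cardiac muscle, endothelial, blood and pluripotency lists had 3, 4, 3 and 1 tested members and were not tested as lists. Named genes were the reporter genes, the 5 largest rises and falls past the threshold (3 and 3 in the comparison that differs in reporter and treatment) among genes with at least 20 CPM in the higher group and no overlap between groups, up to 4 called members of the 7 lists closest to the study's subject (or the 2 most abundant where none passed), up to 3 called members of other lists past camera, and Sox9, Acan, Scx, Mkx and Tnmd.

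The replicate numbers of the labels were checked for pairing. Between eGFP+ and tdTomato+ DMSO libraries, the deviations from the group means of the 3 same-numbered pairs correlated at 0.492 to 0.649, each above the bound of 0.1, so the numbers pair the samples there and blocked values are given there where the block changed the call of a named gene or list, the sign of a named gene or list median, or a count of genes past the threshold. The pairing comes from the data, since the labels do not say what a number marks. Pairs of different numbers reached at most 0.177 between the DMSO groups. For Fsk against DMSO in tdTomato+ cells the 2 same-numbered pairs, at 0.109 and 0.403, also exceeded 0.1, but pairs of different numbers reached 0.312. For Fsk tdTomato+ against DMSO eGFP+ cells the lowest same-numbered pair had 0.0703. In both comparisons with Fsk libraries the block is given only among the alternatives, where it changed counts and some calls. In no pair of libraries did the counts differ as little as sampling noise allows, with a lowest chi-square per degree of freedom of 97.8. Alternatives were DESeq2 1.42.0, limma-voom, RLE scaling, no filter on low counts, at least 1 CPM in at least 3 libraries, only the 2 groups compared, the replicate block, a 2-fold threshold, and each library left out in turn. Chosen after seeing the data were a table without ribosomal RNA and mitochondrial genes, both libraries numbered 3 left out, and the block on the 3 DMSO pairs alone.

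The steps were tested on simulated counts with 50 changed genes at each of 4 fold changes. The counts were drawn around the fit with the replicate block, with its number effects kept. The gain of the blocked fit was therefore built in and says nothing about its gain on the real counts. In the comparison of sorted populations, run on 15303 genes, the fit without a block recovered 0% of 2-fold, 46% of 4-fold, 82% of 8-fold and 96% of 16-fold changes with 0 false calls, and the fit with the block 20%, 94%, 100% and 100% with 10 false calls among 167. In the Fsk comparison, run on 15358 genes, the fit without a block recovered 0%, 36%, 76% and 96% with 0 false calls. Intervals cover the spread between libraries as fitted, and reads without molecular identifiers are not independent molecules. The line's reporter transcripts were not analysed here.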

Results

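Poly(A) RNA from reporter-positive cells of the mouse embryonic stem cell line 3xR was profiled by bulk RNA sequencing at day 14. The line carries an eGFP reporter named for Col2a1, the gene of the main collagen of cartilage, and a tdTomato reporter named for Prg4, the gene of lubricin, a lubricating protein of joint surfaces and tendon sheaths. The 10 libraries fall into 3 groups. There were 4 libraries of Col2a1-eGFP+ cells from cultures given DMSO, the solvent control, and they carry the replicate numbers 1, 3, 4 and 5. There were 3 libraries of Prg4-tdTomato+ cells from DMSO cultures, numbered 1, 3 and 5, and 3 libraries of Prg4-tdTomato+ cells from cultures given Fsk, numbered 1, 4 and 5. Fsk is the label's own abbreviation. It is in common use for forskolin, an activator of adenylyl cyclase, but the labels do not spell it out. Total counts ranged from 15561217 to 20391156 in the eGFP+ DMSO group, from 18023599 to 20408696 in the tdTomato+ DMSO group and from 15355459 to 18988782 in the tdTomato+ Fsk group. The labels do not say whether libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which can be technical. All levels below are read counts scaled to a common library size (CPM), given as mean ± SD, and log2 fold changes are given with their standard error.

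The reporter genes were examined in every library. Col2a1 (ENSMUSG00000022483, protein coding, chromosome 15, 97975602 to 98004695 on the minus strand of GRCm38 in GENCODE M21) stood at 1681 ± 995 CPM in eGFP+ cells (SD, n = 4), 220 ± 157 in tdTomato+ DMSO cells (SD, n = 3) and 33.6 ± 17.8 in tdTomato+ Fsk cells (SD, n = 3). The lowest eGFP+ library held 838 CPM and the highest tdTomato+ DMSO library 390. Within the numbers 1, 3 and 5, the eGFP+ library held 4.48, 7.67 and 23.3 times as much Col2a1 as the tdTomato+ DMSO library of the same number. An exact two-sided permutation test of log2 levels gave p = 0.0286 for eGFP+ against tdTomato+ DMSO cells, the smallest p that 4 against 3 libraries allow, and 0.0857 after Benjamini-Hochberg adjustment over the 6 reporter tests. That test ignores the pairing by number, and the 8 swaps within the 3 pairs are too few for a p below 0.05. Prg4 (ENSMUSG00000006014, protein coding, chromosome 1, 150449412 to 150466165 on the minus strand) was close to the detection limit in all groups, at 1.01 ± 1.17 CPM in eGFP+ cells (SD, n = 4), 0.835 ± 0.389 in tdTomato+ DMSO cells (SD, n = 3) and 0.716 ± 0.0632 in tdTomato+ Fsk cells (SD, n = 3). The tdTomato+ DMSO libraries held 12 to 24 Prg4 reads and the eGFP+ libraries 0 to 37. The log2 fold change of Prg4 between tdTomato+ and eGFP+ DMSO cells was -0.27 (SE 1.08, 95% interval -2.81 to 2.28), but 0.64 (SE 1.13) with the replicate number as a block and 0.89 by limma-voom, so its direction was not settled. The mean log2 difference of the exact two-sided permutation test was 0.14, with p = 0.886. No difference in Prg4 transcript between the sorted populations was detected.

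**Figure D1:**
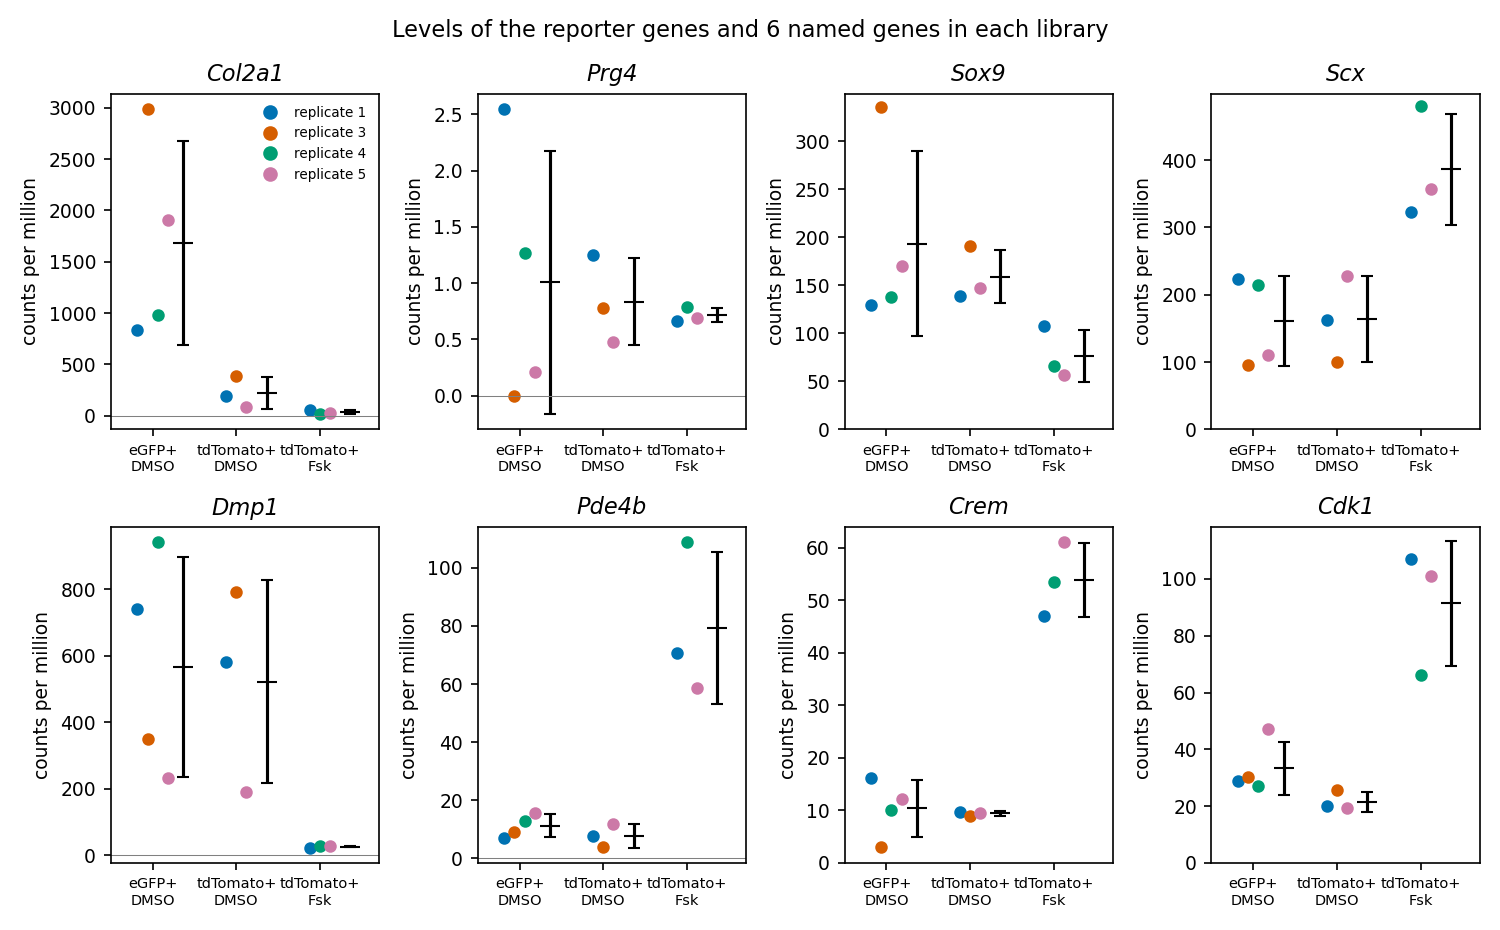
CPM (vertical axes, linear) of the reporter genes Col2a1 and Prg4 and of Sox9, Scx, Dmp1, Pde4b, Crem and Cdk1 in the 10 libraries. Each point is a library coloured by its replicate number, and the black marks give the mean and SD of each group. All 4 eGFP+ libraries lie above the 3 tdTomato+ DMSO libraries for Col2a1, from 838 CPM up, and Prg4 stays below 3 CPM throughout.

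The comparison of Prg4-tdTomato+ with Col2a1-eGFP+ cells in DMSO asks how the sorted populations differ. Genes of the cartilage matrix were lower in tdTomato+ cells. All 23 tested members of the chondrocyte list had a negative log2 fold change, with a median of -1.25, and the list fell by camera's test (adjusted p = 1.0e-26, and adjusted p = 0.0256 with an estimated correlation; n = 3 against 4). With the replicate number as a block the list passed with the preset correlation (adjusted p = 1.9e-28), but its call was lost with an estimated correlation (adjusted p = 0.0542). With that block, used because same-numbered DMSO libraries deviated alike, 7 chondrocyte genes passed the edgeR test over all genes, all of them lower: Ucma, Col11a2, Snorc, Cnmd, Col9a1, Col2a1 and Matn3. Named after their values were seen, except for Col2a1, examples in that blocked fit are Col2a1, with a log2 fold change of -3.36 (SE 0.46, adjusted p = 0.0168), Col11a2, a chain of cartilage collagen XI, at -2.99 (SE 0.30, adjusted p = 0.00283), and Col9a1, a chain of collagen IX, at -3.10 (SE 0.39, adjusted p = 0.0101). Without the block Col2a1 had -2.94 (SE 0.66) and did not pass edgeR's test. DESeq2 (adjusted p = 0.000519) and edgeR without a filter on low counts (adjusted p = 1.1e-06) called it lower.

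Without the block, edgeR's quasi-likelihood test called 0 of 16169 genes at an adjusted p below 0.05, and the smallest adjusted p was 0.339. Unadjusted p-values below 0.05 were found for 221 genes, against 808 expected by chance. DESeq2 called 13 genes and limma-voom 0. With the block, edgeR called 14 genes, all lower in tdTomato+ cells and all by at least 2-fold. The 7 of these outside the chondrocyte list were Comp, a matrix protein of cartilage and tendon, Meltf, Colgalt2, Scrg1, T (brachyury, a transcription factor of mesoderm and notochord), the carboxypeptidase gene Cpm and the surface protein gene Cd24a, and they are named here after their values were seen. Their blocked log2 fold changes ranged from -2.06 (SE 0.30) for Comp to -3.44 (SE 0.44) for Scrg1. T stood at 4.54 ± 4.26 CPM in tdTomato+ cells (SD, n = 3) and 26.3 ± 18.1 in eGFP+ cells (SD, n = 4). The blocked count fell to 1 gene without eGFP+ replicate 3, to 3 without tdTomato+ replicate 1, and to 2 without tdTomato+ replicate 3 or without tdTomato+ replicate 5. The count is therefore not stable. Each of these leave-outs also breaks a pair, so the losses cannot be assigned to single libraries. The count was 16 without eGFP+ replicate 1, 19 without eGFP+ replicate 4 and 17 without eGFP+ replicate 5. Blocked values come from a fit of all 10 libraries, Fsk libraries included, except where the 3 DMSO pairs alone are named. The pairing by number was less clear for the Fsk libraries. With the block on the 3 DMSO pairs alone, a choice made after seeing the data, edgeR called 68 genes.

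The fixed lists place the rest of this comparison. Adjusted over the list alone, 10 chondrocyte genes were lower in tdTomato+ cells and no gene of another list passed. With the block these were 15 chondrocyte and 4 epithelial and endoderm genes and 1 joint gene lower and 1 BMP target higher. The transcription factor gene Sox9, which drives the chondrocyte programme, had a log2 fold change of -0.28 (SE 0.38, adjusted p = 1.0), and Acan, the gene of aggrecan, had -0.54 (SE 0.52, adjusted p = 1.0). Neither passed, with or without the block. The tendon list did not pass, with a median of 0.04 over 18 tested genes (adjusted p = 0.937). Scx, a transcription factor gene of tendon progenitors, stood at 164 ± 64.0 CPM in tdTomato+ (SD, n = 3) and 161 ± 67.2 in eGFP+ cells (SD, n = 4). The tendon genes Mkx and Tnmd had log2 fold changes of 0.36 (SE 0.51) and -0.54 (SE 0.69), and neither passed. Of the tendon list's most abundant genes, Lox, a collagen cross-linking enzyme, had 0.45 (SE 0.45) and Ptgs2 0.06 (SE 0.51). Col1a1 stood at 9746 ± 2516 CPM in tdTomato+ cells (SD, n = 3) and 5260 ± 1707 in eGFP+ cells (SD, n = 4), with a log2 fold change of 0.89 (SE 0.49) that did not pass. Fn1, in the same fibrous matrix list, had 0.24 (SE 0.53).

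Of 23 lists with 5 or more tested genes, 5 passed camera. Besides the chondrocyte list, the matrix proteinases rose (median 0.38 over 17 genes, adjusted p = 0.00911), and 3 lists fell: epithelial and endoderm markers (median -1.74 over 6 genes, adjusted p = 0.00132), cell cycle genes (median -0.55 over 24 genes, adjusted p = 0.0262) and mitochondrially encoded genes (median -0.26 over 13 genes, adjusted p = 0.0208). None of these 4 lists had a member past the edgeR test. With an estimated correlation their adjusted p-values were 0.328, 0.328, 0.741 and 0.741, so that without the block only the chondrocyte call held there. With the block and the preset correlation, 7 lists passed. The mitochondrial list was then lost (adjusted p = 0.0946) and the lists of fibrous matrix (0.0414), hypoxia and glycolysis (0.0084) and unfolded protein and amino acid stress (0.00666) were gained, but with the block and an estimated correlation these 3 had 0.767, 0.653 and 0.386 and no list passed. Calls other than that of the chondrocyte list did not hold in each leave-out, which also leaves fewer libraries to test with. The cell cycle median was 0.38 without eGFP+ replicate 5 (adjusted p = 0.858) and -0.40 without tdTomato+ replicate 1 (adjusted p = 0.815). The mitochondrial median was 0.07 without tdTomato+ replicate 5 (adjusted p = 0.686), and its adjusted p was 0.184 without eGFP+ replicate 1, 0.106 without eGFP+ replicate 4 and 0.0663 without tdTomato+ replicate 3. The matrix proteinases had an adjusted p of 0.0732 without eGFP+ replicate 5 and 0.474 without tdTomato+ replicate 1, and the epithelial list one of 0.118 without tdTomato+ replicate 1. In the epithelial list Krt8, named after its values were seen, stood at 6.04 ± 7.83 CPM in tdTomato+ (SD, n = 3) and at 22.2 ± 19.9 in eGFP+ cells (SD, n = 4). The other 18 lists had adjusted p-values from 0.156 to 0.937 without the block. Among them, the hypertrophic cartilage and osteoblast list had Spp1 at -1.01 (SE 0.83) and Dmp1 at -0.12 (SE 0.53). In the joint and superficial zone list Thbs1 had -0.27 (SE 0.72) and Cd44 -0.07 (SE 0.54). In the AP-1 and NFI list Junb had 0.10 (SE 0.35) and Jun 0.17 (SE 0.38), and in the cAMP list Nr4a1 had -0.10 (SE 0.56) and Fosb 0.03 (SE 0.46). None of these genes passed. With the block Fn1, Dmp1 and Nr4a1 had the opposite sign, at -0.015 (SE 0.42), 0.020 (SE 0.47) and 0.14 (SE 0.35), and none passed. The medians of 4 lists also changed sign with the block, from -0.051 to 0.18 for hedgehog targets, from -0.079 to 0.060 for BMP targets, from -0.026 to 0.10 for the cAMP list and from 0.021 to -0.0058 for the joint list, and these did not pass either.

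Fsk was compared with DMSO in Prg4-tdTomato+ cells to ask what the treatment changed within the sorted population. In Fsk cells 48 genes rose and 44 fell (edgeR's quasi-likelihood test, 16169 genes, Benjamini-Hochberg adjusted p below 0.05, n = 3 against 3), each by at least 2-fold. In the list of cAMP and CREB targets, the genes of the phosphodiesterases Pde4b and Pde10a, enzymes that degrade cyclic nucleotides, and of the transcription factor Crem rose by 3.34 (SE 0.47), 2.56 (SE 0.39) and 2.52 (SE 0.48) on the log2 scale. Dmp1, a mineralised matrix gene of osteocytes, fell by 4.30 on the log2 scale (SE 0.65), and the cell cycle kinase gene Cdk1 rose by 2.09 (SE 0.33). The chondrocyte and bone lists were lower and the cell cycle and interferon lists higher by camera's test, none of them with an estimated correlation.

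Among genes of at least 20 CPM whose groups did not overlap, the largest rises were those of Mmp12, Shisal1, Scg2, Syt13 and Mmp9. Mmp12 (ENSMUSG00000049723, chromosome 9, 7344381 to 7369499), a macrophage-type elastase, went from 0.0787 ± 0.0782 to 55.7 ± 65.6 CPM (SD, n = 3 each), with 3, 0 and 2 reads in the DMSO libraries and 2167, 259 and 428 in the Fsk libraries. Its log2 fold change of 9.35 (SE 1.32, adjusted p = 0.0118) rests on those few DMSO reads. Shisal1 (ENSMUSG00000062760, chromosome 15, 84379203 to 84447097) rose by 6.78 (SE 0.86, adjusted p = 0.0079) and Scg2 (ENSMUSG00000050711, chromosome 1, 79434669 to 79440120), a secretory granule protein of neuroendocrine cells, by 6.65 (SE 0.74, adjusted p = 0.00506). Syt13 rose by 5.65 (SE 0.93) and Mmp9, a gelatinase, by 5.18 (SE 0.97), and both varied widely between Fsk libraries, at 66.8 ± 65.8 and 66.9 ± 95.4 CPM (SD, n = 3). The largest falls were those of Ace, the angiotensin converting enzyme gene (-5.71, SE 1.13), Cpne7 (-4.66, SE 0.77), Dmp1 (ENSMUSG00000029307, chromosome 5, 104202613 to 104214102; -4.30, SE 0.65), the laminin chain gene Lamb3 (-4.07, SE 0.71) and Rgs16, a regulator of G protein signalling (-3.92, SE 0.77). Their adjusted p-values lay between 0.0118 for Dmp1 and 0.0395 for Ace and Rgs16. Some of these changes were smaller when a single library was left out, most so for Mmp9, and all kept their direction. Without Fsk replicate 1 the log2 fold changes of Mmp9, Syt13 and Mmp12 were 2.69, 4.45 and 7.71, and without DMSO replicate 3 those of Ace, Cpne7, Lamb3 and Rgs16 were -3.95, -3.34, -3.50 and -3.30. Mmp9 and Syt13 passed only without Fsk replicate 4 or 5, Ace only without DMSO replicate 5, and Rgs16 in none of the 6 leave-outs. Mmp12 lost its call without Fsk replicate 1, Cpne7 and Dmp1 without any of the 3 Fsk libraries, and Lamb3 without DMSO replicate 3, Fsk replicate 4 or Fsk replicate 5.

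In the list of cAMP and CREB targets, 3 of 19 tested genes rose over all genes tested and none fell. Pde4b (ENSMUSG00000028525, chromosome 4, 102087543 to 102607259) went from 7.80 ± 4.04 to 79.3 ± 26.2 CPM (SD, n = 3 each), Pde10a from 9.50 ± 2.44 to 56.1 ± 10.3, and Crem (ENSMUSG00000063889, chromosome 18, 3266048 to 3337748) from 9.39 ± 0.443 to 53.9 ± 7.02. Adjusted over the list alone, 5 genes were higher and 1 lower. The list as a whole did not pass camera (median 0.21, adjusted p = 0.0856, and adjusted p = 0.319 with an estimated correlation). By fry it passed (adjusted p = 0.0476), but not with the replicate block (adjusted p = 0.106). Its member Fosb, named after its values were seen, had a log2 fold change of -1.24 (SE 0.50, adjusted p = 0.375).

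Of 24 tested cell cycle genes, all had a positive log2 fold change, with a median of 2.88. The list rose by camera (adjusted p = 1.1e-19), but its adjusted p was 0.261 with an estimated correlation. Cdk1 (ENSMUSG00000019942, chromosome 10, 69335146 to 69352938) was the only member past the threshold over all genes, at 91.5 ± 22.1 against 21.5 ± 3.54 CPM (SD, n = 3 each). Adjusted over the list alone, 21 genes were higher. Ccnb1, named after its values were seen, stood at 61.3 ± 27.5 against 4.45 ± 2.42 CPM (adjusted p = 0.068 over all genes by edgeR). The interferon response list rose as well (median 1.78 over 10 genes, adjusted p = 2.0e-05, and 0.278 with an estimated correlation) with 0 members past the threshold over all genes and 2 higher adjusted over the list alone. Mitochondrially encoded genes rose by camera (median 0.70 over 13 genes, adjusted p = 0.00045, and adjusted p = 0.368 with an estimated correlation), and lost that call without DMSO replicate 5 (median 0.41, adjusted p = 0.14). Their share of counts was 4.85 ± 1.24% in Fsk and 3.29 ± 1.46% in DMSO libraries (SD, n = 3 each).

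The hypertrophic cartilage and osteoblast list fell, with a median of -2.52 over 12 genes (adjusted p = 3.5e-07, and adjusted p = 0.0653 with an estimated correlation). Dmp1 and Mef2c, a transcription factor gene of chondrocyte hypertrophy, passed over all genes, and 7 members were lower adjusted over the list alone. Mef2c had a log2 fold change of -2.06 (SE 0.39, adjusted p = 0.0318). The chondrocyte list fell by camera (median -0.78 over 23 genes, adjusted p = 0.00346, and adjusted p = 0.319 with an estimated correlation). It did not pass with the replicate block (camera adjusted p = 0.123) or by fry (adjusted p = 0.155). Its members went both ways, 16 down and 7 up, with Ucma, named after its values were seen, at 4.29 (SE 1.18, adjusted p = 0.146). Over all genes 0 members passed the threshold, and 5 were lower and 1 higher adjusted over the list alone. Col2a1 had a log2 fold change of -2.71 (SE 0.67, adjusted p = 0.106) and was lower in every Fsk library than in every DMSO library, and an exact permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. Col2a1 passed by DESeq2 (adjusted p = 0.000837), without a filter on low counts (3.1e-06), in a fit of the 2 compared groups alone (0.0287) and narrowly with the replicate block (0.0496). Its adjusted p over the alternatives reached 0.249. Sox9 had -1.06 (SE 0.41, adjusted p = 0.359) and Acan -1.50 (SE 0.56, adjusted p = 0.329), and Acan passed without a filter. Col11a1 and Col9a3, the most abundant of the list, had -0.47 (SE 0.50) and 1.07 (SE 0.58).

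Without a block, tendon and fibrous matrix genes did not pass as lists. The tendon list had a median of -0.40 over 18 genes (adjusted p = 0.413), with 1 gene higher and 4 lower adjusted over the list alone. Scx stood at 387 ± 82.4 CPM in Fsk and 164 ± 64.0 in DMSO cells (SD, n = 3 each). All 3 Fsk libraries lay above all 3 DMSO libraries for Scx, but the log2 fold change of 1.24 (SE 0.43) did not pass (adjusted p = 0.279). Mkx had 0.65 (SE 0.55), Tnmd 0.03 (SE 0.73), Tnc 0.21 (SE 0.47) and Lox -1.59 (SE 0.50), and none passed. In the fibrous matrix list Thbs2, a matrix glycoprotein gene, fell by 2.60 on the log2 scale (SE 0.46, adjusted p = 0.0236), while the list did not pass (adjusted p = 0.221). In the joint and superficial zone list, which did not pass either (adjusted p = 0.142), Thbs1 had -2.26 (SE 0.80) and Cd44 -0.42 (SE 0.57). DESeq2 and the fit without a filter called Thbs1 and Lox lower.

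The AP-1 and NFI list fell by camera (median -0.60 over 14 genes, adjusted p = 0.0349, and adjusted p = 0.319 with an estimated correlation). The call was lost without DMSO replicate 1 (adjusted p = 0.122), DMSO replicate 5 (0.0798), Fsk replicate 4 (0.0908) or Fsk replicate 5 (0.0555). Its only member past the threshold was Atf3, a stress-induced transcription factor gene, which fell by 2.31 (SE 0.45, adjusted p = 0.0359). Adjusted over the list alone, 2 genes were lower and 2 higher. The higher pair, named after their values were seen, were the nuclear factor I genes Nfib and Nfia, with log2 fold changes of 2.09 (SE 0.66) and 1.44 (SE 0.50) and adjusted p-values of 0.22 and 0.28 over all genes by edgeR. Atf3 is also the member that passed in the list of dissociation and heat shock genes, which fell (median -0.29 over 21 genes, adjusted p = 0.0149, and adjusted p = 0.261 with an estimated correlation) and had 4 members lower adjusted over the list alone. The remaining lists had adjusted p-values from 0.0603, for the matrix proteinases, to 0.877.

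The count of 92 fell in each leave-out. A leave-out also leaves fewer libraries to test with, so the losses cannot be assigned to single libraries. It was 39 without tdTomato+ DMSO replicate 1, 29 without DMSO replicate 3, 75 without DMSO replicate 5, 22 without Fsk replicate 1, 27 without Fsk replicate 4 and 29 without Fsk replicate 5. In the same order, 8, 7, 11, 4, 8 and 7 of the 17 named genes past the threshold stayed past it. Of these 17, Pde4b, Scg2 and Shisal1 passed in each of the 6 leave-outs, while Crem and Rgs16 passed in none of them. The log2 fold change of Crem nevertheless stayed between 2.43 and 2.61, and that of Dmp1 between -4.69 and -3.87. A lost call thus does not by itself mean a smaller change. Cdk1 passed without DMSO replicate 3 and without Fsk replicate 4, and not in the other leave-outs, where its adjusted p reached 0.0676. By limma-voom 7 of the 17 did not pass: Mmp12, Mmp9, Ace, Cpne7, Rgs16, Mef2c and Atf3.

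**Figure D2:**
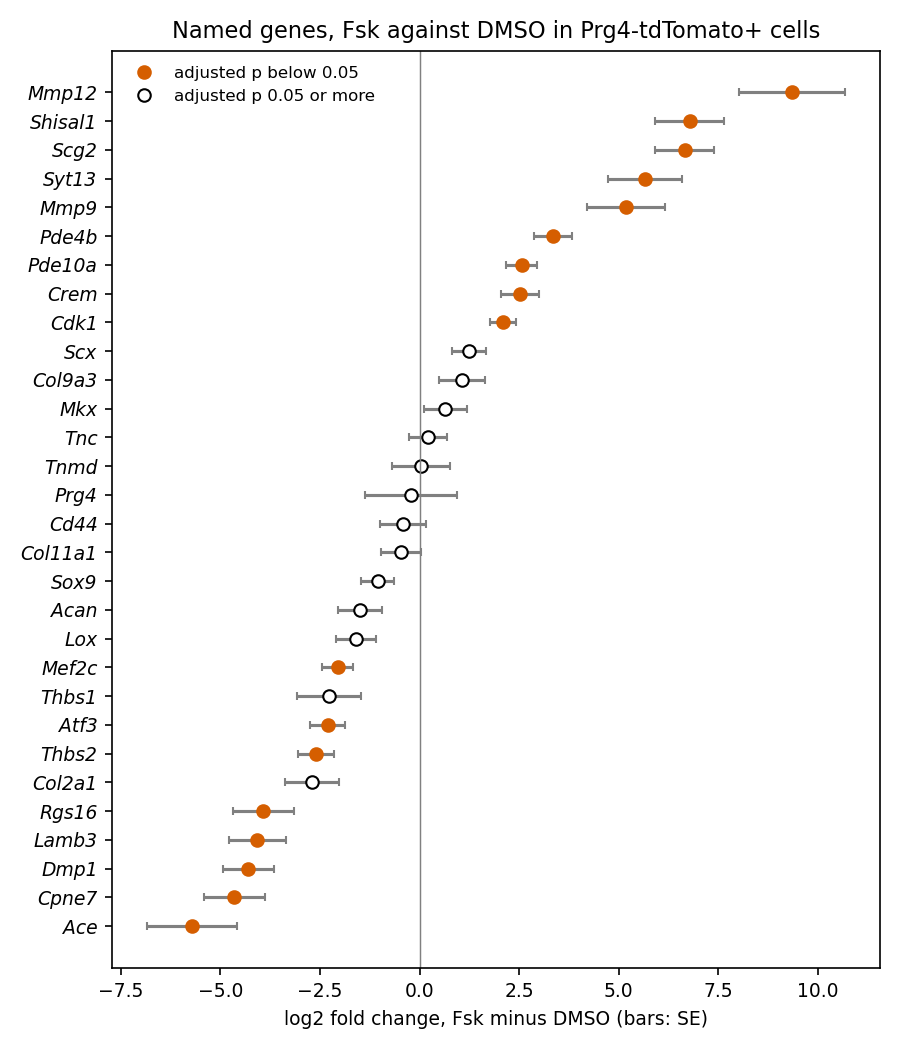
Log2 fold change (horizontal axis, Fsk minus DMSO) with its standard error as a bar for each named gene in Prg4-tdTomato+ cells, n = 3 against 3. Filled points have an edgeR adjusted p below 0.05. Mmp12 is highest at 9.35 and Ace lowest at -5.71, and Scx at 1.24 and Col2a1 at -2.71 are open points.

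The Fsk-treated tdTomato+ cells were also compared with DMSO eGFP+ cells, which differ in both reporter and treatment, so the effects of the 2 cannot be separated here. Of 16169 genes, 104 were higher and 116 lower in Fsk tdTomato+ cells (edgeR, adjusted p below 0.05, n = 3 against 4). Cartilage genes fell: 8 of 23 chondrocyte genes were lower over all genes and 18 adjusted over the list alone, with a median of -1.96 (camera adjusted p = 8.1e-20, and adjusted p = 0.0299 with an estimated correlation). Col2a1 fell by 5.64 on the log2 scale (SE 0.76, adjusted p = 0.00473), Comp had -5.57 (SE 0.73, adjusted p = 0.00424) and T had -5.69 (SE 0.94, adjusted p = 0.0118). Rises were ranked among genes of at least 20 CPM whose groups did not overlap. The largest were those of Mmp12 (9.11, SE 1.16, adjusted p = 0.00424), Shisal1 (6.97, SE 0.77, adjusted p = 0.0021) and Scg2 (6.51, SE 0.65, adjusted p = 0.00139). Mmp12 was absent from 3 of the 4 eGFP+ libraries, with 6 reads in eGFP+ replicate 1. Its log2 fold change was 7.45 without Fsk replicate 1 and reached 13.0 in another leave-out, so its size is poorly fixed.

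The hypertrophic cartilage and osteoblast list fell as well (median -2.74 over 12 genes, 3 lower over all genes and 9 adjusted over the list alone, adjusted p = 5.7e-08, and adjusted p = 0.0299 with an estimated correlation). The other calls were lost with an estimated correlation. They were rises of the cell cycle list (median 2.27, adjusted p = 1.5e-14, then 0.223), the interferon list (median 1.23, adjusted p = 5.3e-05, then 0.234) and the matrix proteinases (median 0.87, adjusted p = 0.000122, then 0.0796), and a fall of the dissociation and heat shock list (median -0.37, adjusted p = 0.00185, then 0.0894). The other 17 lists had adjusted p-values from 0.0749 to 0.936. Scx had a log2 fold change of 1.26 (SE 0.39, adjusted p = 0.16), Mkx 1.01 (SE 0.51), Tnmd -0.52 (SE 0.69), Sox9 -1.34 (SE 0.39, adjusted p = 0.14) and Acan -2.04 (SE 0.55, adjusted p = 0.0996), and none of these passed. DESeq2 and the fit without a filter called Scx higher and Sox9 and Acan lower, and limma-voom did not call T. The count of 220 was 80 without eGFP+ replicate 4, 469 without eGFP+ replicate 5, 58 without Fsk replicate 1, 78 without Fsk replicate 4 and 51 without Fsk replicate 5. T lost its call without any of the 3 Fsk libraries, and the other 5 named genes kept theirs in all 7 leave-outs.

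**Figure D3:**
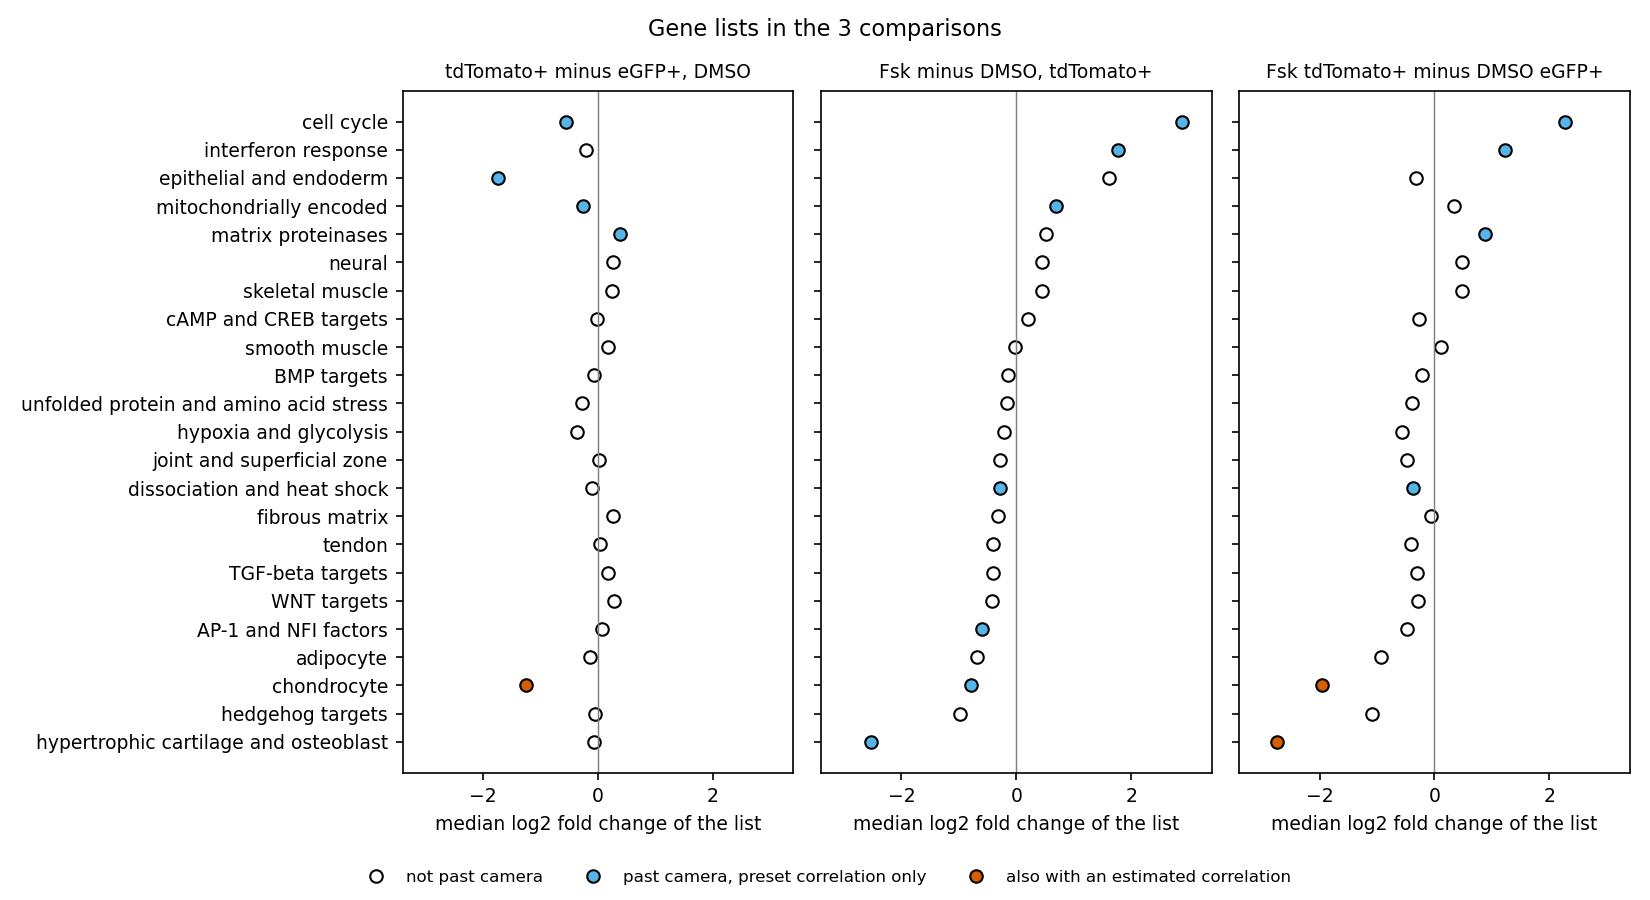
Median log2 fold change (horizontal axes) of the 23 tested gene lists in the 3 comparisons. Open points did not pass camera, blue points passed with the preset correlation only, and orange points passed also with an estimated correlation. The chondrocyte list is orange at -1.25 and -1.96 in the comparisons with eGFP+ cells, and the cell cycle list lies at 2.88 for Fsk against DMSO in tdTomato+ cells.

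Across genes, the fold changes of the reporter comparison in DMSO and of the Fsk comparison were set against each other. Both use the tdTomato+ DMSO libraries, with opposite sign, so chance alone gives a negative correlation. Over 16169 genes, which are not independent replicates, Pearson's r was -0.25 and Spearman's rho -0.321. Unchanged groups simulated around the same libraries gave r = -0.532 (SD 0.00968 over 20 draws), or -0.544 (SD 0.00958) when the effects of the replicate numbers were kept. The observed covariance was -0.151, against -0.284 and -0.243 in the simulations. The difference of covariances was 0.133 and 0.0924. The 3 shared libraries cannot be split into parts of at least 2, so the relation could not be computed on separate libraries.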

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

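The explanations weighed in this part and their bounds were chosen after the results they measure were seen, unlike the search for outlying libraries. Leaving out a library, the replicate block and the estimated correlation were alternatives fixed beforehand, but their use as tests here was not. In the eGFP+ group, the only group of 4, 46 sets of values (named genes and library measures) were searched for a library far from the other 3. There were 4, against about 2.3 expected by chance, since chance marks about 1 in 20. Fn1 stood at 8479 CPM in eGFP+ replicate 3, with the others between 4980 and 5442. Rgs16 stood at 159 in eGFP+ replicate 3, with the others between 14.9 and 37.7. Cdk1 stood at 47.3 in eGFP+ replicate 5, with the others between 27.0 and 30.3. Mmp12 stood at 0.413 in eGFP+ replicate 1 and at 0 in the others. Replicate 3 also had the lowest TMM factor of the 10 libraries, 0.683, and the fewest detected genes, 16626.

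Few genes were called between tdTomato+ and eGFP+ cells in DMSO, 0 without and 14 with the replicate block, although Col2a1 separated the libraries. Without eGFP+ replicate 3, the library that stands apart, 0 genes were called as well, but a count of 0 that stays 0 with fewer libraries decides nothing, and with the block that count fell from 14 to 1. Differences between cultures that share a number may hide part of the reporter difference, since all 3 same-number pairs deviated together, with a lowest correlation of 0.492. Whether the number marks a day, a culture or a batch is open. The difference between cartilage-like and other cells that the reporters name would add calls, so it does not account for their small number. It stays a possible biological explanation of the 14 calls with the block, and was not tested as their cause. With 0 real calls each of the 35 splits of the 7 libraries gives as many by construction, so this says nothing about chance, and the highest other split gave 2. At an unadjusted p under 0.05 the real split gave 221 genes, 23 of 35 splits gave as many, and a split that set eGFP+ replicate 5 and tdTomato+ replicates 3 and 5 apart gave 3456, which points to a structure of the samples other than the reporter. Only 8 splits part each same-numbered pair as the real one does, too few for a share under 0.05, and the highest other of these gave 204 genes. For the chondrocyte list the real median was -1.25 and the highest other of these 8 was 1.246. That other split is the real one turned round, with only eGFP+ replicate 4 on the side of the tdTomato+ libraries. Its value was thus largely set by the real difference, and the next furthest from 0 was -0.858. Of all 35 splits 1, the real one, lay as far from 0. These 35 ignore the pairing, and the list's adjusted p was 0.0542 with the block and an estimated correlation. With the block, 8 swaps within the 3 pairs are too few for a share under 0.05. The real grouping gave 14 calls and the highest other 2, and 1 of the 8 gave as many as the real one, itself. Those 2 calls came from swapping all 3 pairs, which turns the real grouping round except for eGFP+ replicate 4. Each swap of fewer pairs gave 0 calls.

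No difference in Prg4 transcript was detected in the cells sorted on the Prg4-tdTomato reporter. Exchanged sort labels are argued against by Col2a1, whose lowest eGFP+ level was 2.15 times the highest tdTomato+ level in DMSO. Too few Prg4 reads may be the reason, because the 95% interval of the log2 fold change reaches up to 2.28. Reporter protein that outlasts the transcript cannot be told apart, because the table has 0 genes named for a reporter.

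Cell cycle genes were higher with Fsk in tdTomato+ cells, with a median of 2.88. Pluripotent cells left in the Fsk libraries are argued against by their markers, of which none exceeded 1.09 CPM in an Fsk library, while Cdk1 stood at 91.5 with Fsk and 21.5 in DMSO. Library scaling moves every gene alike and is argued against by the list's median, which lay 2.90 above the median of all genes. Culture differences that follow the number do not carry the whole shift, since the median was 3.39 with the replicate block. Cells of another type among the Fsk cells were not excluded. Of 6 epithelial and endoderm genes 5 had a positive log2 fold change with Fsk, none past the threshold over all genes or over the list alone (median 1.62, adjusted p = 0.0718), and Fsk replicate 1 held 36.9 CPM of Krt18, 20.6 of Krt8, 3.45 of Cdh1 and 5.76 of the endothelial gene Cdh5. Without that library the cell cycle median was 2.30. An effect of Fsk on proliferation, or on which cells pass the sort, stays open as well, and the list's adjusted p of 0.261 with an estimated correlation leaves the call itself unsettled.

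For the count of genes in the Fsk comparison, 10 splits of 3 against 3 libraries are too few for a share under 0.05. The real split gave 92 calls, the highest other 0, and 1 split gave as many as the real one, itself. For Fsk tdTomato+ against DMSO eGFP+ cells, 1 of 35 splits gave as many calls as the real 220, itself. That is the smallest share that 35 splits allow, so it argues against chance for that count without excluding it. These splits ignore the replicate numbers, whose same-numbered pairs correlated at 0.0703 to 0.443 there. On some other measures the real split was not alone. At an unadjusted p under 0.05 the real split gave 1930 genes, 4 of 35 splits gave as many and the highest other gave 3100. The cell cycle median was 2.27, and 3 of 35 splits lay as far from 0, the highest other at 3.18. The highest other split by calls gave 44 and set eGFP+ replicates 1, 3 and 4 apart from eGFP+ replicate 5 and the Fsk libraries. The 3100 genes and the cell cycle median 3.18 from 0 came from that same split. It differs from the real one only in its direction and in the side of eGFP+ replicate 5, so it is not unrelated to the real grouping.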

How the results depend on the processing

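Leaving out ribosomal RNA and mitochondrial genes, leaving out both libraries numbered 3, and the block on the 3 DMSO pairs alone were chosen after seeing the data. RLE scaling, a minimum of 1 CPM in 3 libraries, limma-voom and the table without ribosomal RNA and mitochondrial genes kept each count of genes within 1.5 times, though not each call. Except where said, the cause of a change was not tested. The correlation of fold changes across genes ranged from -0.572 without a filter to -0.125 without eGFP+ replicate 5. A negative value follows from the shared libraries alone, and no value for unchanged groups was computed under the alternatives, so the sign says nothing about the relation. It was not run on the 2 compared groups alone. Of the named genes' values outside the leave-outs, 521 kept direction and side of the threshold, 23 passed newly, 17 no longer passed and 17 reversed. For Fsk against DMSO, calls were lost by limma-voom for Mmp12, Mmp9, Ace, Cpne7, Rgs16, Mef2c and Atf3, without a filter for Ace, in the 2 groups alone for Mmp9 and Ace, and without libraries numbered 3 for Mmp9, Ace, Lamb3, Thbs2, Atf3 and Pde10a. T lost its call by limma-voom in the last comparison.

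Between tdTomato+ and eGFP+ cells in DMSO, DESeq2 called 13 genes, no filter 18, the replicate block 14 and the block on the 3 pairs 68, against 0. For Fsk against DMSO, DESeq2 called 566, no filter 462, the replicate block 508, the 2 groups alone 260 and the fit without libraries numbered 3 50, against 92. For Fsk tdTomato+ against DMSO eGFP+ cells, DESeq2 called 798, no filter 800 and the replicate block 820, against 220. Between the DMSO groups the block changed no call of a named gene or list other than those given with that comparison. The leave-outs gave 22 to 75 and 51 to 469 genes in the last 2 comparisons. Of gene lists, 1, 0 and 2 passed with an estimated correlation in the 3 comparisons, against 5, 7 and 6, and 1, 5 and 6 passed by fry. For Fsk against DMSO, fry called the cAMP and TGF-beta lists (adjusted p = 0.0476 each), which camera had not. It did not call the chondrocyte (0.155), interferon (0.0797), mitochondrial (0.251) and AP-1 and NFI (0.15) lists. In the last comparison it called the cAMP list (0.018) and not the interferon list (0.0503). Without a filter 11 passed in each comparison with Fsk. The leave-outs gave 3 to 6 lists in the first comparison and 6 to 10 in the last. With the replicate block, 8 and 6 lists passed in the comparisons with Fsk. For Fsk against DMSO, the chondrocyte list lost its call with that block (adjusted p = 0.123), and the epithelial and endoderm list (median 1.69, adjusted p 0.00332 against 0.0718) and the tendon list (median -0.52, 0.0406 against 0.413) gained one, lost again with an estimated correlation (0.391 each). Of the 14 genes lower in tdTomato+ DMSO cells with the block, 3 were lower and 4 (Ucma, Cpm, Cd24a and Scrg1) higher with Fsk in that fit, where Col2a1 (-1.91, adjusted p = 0.0496), Col9a3 (1.32, adjusted p = 0.0207) and Thbs1 (-1.66, adjusted p = 0.0446) passed newly. Over the alternatives their adjusted p-values ranged from 3.1e-06 to 0.249, from 0.0207 to 0.792 and from 0.000628 to 0.768. Acan passed newly for Fsk tdTomato+ against DMSO eGFP+ cells (-2.33, adjusted p = 0.00324, range 0.000106 to 0.0996). With the block and an estimated correlation 0 lists passed in each of the 3 comparisons. The chondrocyte and bone lists of Fsk tdTomato+ against DMSO eGFP+ cells, which held at 0.0299 without the block, then had 0.123 and 0.164. Of 10 libraries, 8 correlated best with a library of their own replicate number, with correlations of same-numbered pairs from 0.109 to 0.403 for Fsk against DMSO and from 0.0703 to 0.443 for Fsk tdTomato+ against DMSO eGFP+, a hint from the data and not from the design.

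The values that reversed belong to genes that had not passed, and to 2 lists. Between the DMSO groups they were Prg4 at 0.89 (limma-voom), 0.64 (block) and 1.04 (block on 3 pairs), Ptgs2 at -0.0048 (limma-voom) and -0.12 (block on 3 pairs), Nr4a1 at 0.040 (limma-voom), 0.14 (block) and 0.12 (block on 3 pairs), Dmp1 at 0.020 (block) and 0.17 (block on 3 pairs), Fn1 at -0.015 (block), and, without libraries numbered 3, Cd44 at 0.077 and Fosb at -0.11. For Fsk against DMSO they were Tnmd at -0.40 (replicate block) and -0.31 (without libraries numbered 3) and Cd44 at 0.052 (replicate block). Prg4 was 0.82 by limma-voom for Fsk tdTomato+ against DMSO eGFP+. Leave-outs crossed 0 between the DMSO groups for the cell cycle list (-0.82 to 0.38), the mitochondrial list (-0.88 to 0.071), Cd44 (-0.59 to 0.31), Dmp1 (-0.55 to 0.28), Fn1 (-0.26 to 0.56), Fosb (-0.24 to 0.34), Jun (-0.054 to 0.39), Junb (-0.035 to 0.29), Nr4a1 (-0.79 to 0.55), Prg4 (-0.68 to 0.73), Ptgs2 (-0.25 to 0.41), Scx (-0.29 to 0.28), Sox9 (-0.43 to 0.12) and Thbs1 (-1.35 to 0.16). For Fsk against DMSO they did for Cd44 (-0.80 to 0.11), Prg4 (-0.50 to 0.20), Tnc (-0.069 to 0.67) and Tnmd (-0.32 to 1.04), and in the last comparison for Prg4 (-0.88 to 0.52).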

Other observations

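The osteoclast test without Ctsk and the genes named singly were chosen after their values were seen. In tdTomato+ cells each gene below passed edgeR's test between Fsk and DMSO unless said otherwise (n = 3 against 3). Npy, the gene of neuropeptide Y, went from 0.683 ± 0.24 to 11.8 ± 7.56 CPM (log2 fold change 4.09, SE 0.79, adjusted p = 0.0343), and Gap43, a growth cone protein gene, from 0.946 ± 0.426 to 15.9 ± 13.8 (adjusted p = 0.0388). Gpha2, a glycoprotein hormone subunit gene, went from 7.87 ± 7.47 to 188 ± 113 (adjusted p = 0.036). The neural marker list fixed beforehand did not pass (median 0.45 over 9 genes, adjusted p = 0.294). Igfbp2, which binds insulin-like growth factors, went from 44.9 ± 12.4 to 854 ± 588 CPM (log2 fold change 4.25, SE 0.57, adjusted p = 0.0104), and Wif1, a WNT antagonist gene, rose by 3.08 (SE 0.55, adjusted p = 0.0238). A phosphodiesterase outside the fixed list, Pde3b, rose by 3.88 (SE 0.57, adjusted p = 0.0118).

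The pair that controls osteoclast formation moved apart. Tnfsf11, the gene of the ligand RANKL, rose from 2.30 ± 1.04 to 30.8 ± 8.76 CPM (log2 fold change 3.75, SE 0.55, adjusted p = 0.0118), and Tnfrsf11b, the gene of its decoy receptor osteoprotegerin, fell from 24.4 ± 11.8 to 2.07 ± 0.479 (log2 fold change -3.55, SE 0.49, adjusted p = 0.0112; SD, n = 3 each). Of other genes, Cspg4, a pericyte and progenitor proteoglycan gene, fell from 321 ± 161 to 32.2 ± 7.81 CPM (adjusted p = 0.0118), Timp3, an inhibitor of matrix proteinases, fell by 2.68 on the log2 scale (SE 0.49) and Col8a1 by 3.58 (SE 0.55). Cd34 rose from 8.55 ± 3.69 to 55.6 ± 26.5 CPM (adjusted p = 0.0225) and Cpm from 6.26 ± 2.08 to 54.7 ± 21.4 (adjusted p = 0.0118). Of the hedgehog list, which did not pass (adjusted p = 0.113), Foxf2 fell by 2.80 (SE 0.49, adjusted p = 0.0228).

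A further test used 8 osteoclast genes listed before their values were seen, to ask whether osteoclast precursors were among the Fsk cells. It does not show what moved Tnfsf11 and Tnfrsf11b. Without such cells each gene was to stay under 5 CPM, but Ctsk reached 50.3 in an Fsk library. Ctsk averaged 79.1 in DMSO and 40.9 with Fsk, so its level is not specific to Fsk cells and that bound decides nothing. Judged without Ctsk, a choice made after seeing it, the other 7 genes reached at most 1.19 CPM (Acp5), which argues against such cells. A sort for tdTomato would remove cells that lack the reporter.

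The notochord gene T and Cd24a were lower in tdTomato+ than in eGFP+ cells with the block, so notochord-like cells among the eGFP+ cells were a candidate explanation. Markers not yet looked at were listed before the test. Of the 6 that could be tested, 4 had a negative and 2 a positive log2 fold change with the block, none past the threshold, with a median of -0.39 (SD 1.58). Noto was too low to test, at 0 CPM in eGFP+ and 0.0798 in tdTomato+ DMSO cells. So was Foxa2, looked at before, at 0.0749 and 0.0665. The keratin genes Krt8, Krt18 and Krt19, also looked at before, had -2.86, -2.36 and -2.55 with the block, none past the threshold. The most negative was Shh, at -3.43 (SE 1.42, adjusted p = 0.835) and 1.15 CPM in eGFP+ cells, and Car3 had -2.12 (SE 0.39, adjusted p = 0.108) at 16.1 CPM. Cdh2, Hspb1 and Basp1, which many cells express, had 0.67, -0.21 and 0.32, and Foxa1 had -0.56. A median above -0.5 was to count against such cells, but the members went both ways by more than that margin, so the question stays open.

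Of the lists too small to test, the highest level in any library was 62.7 CPM (Tnnt2) for cardiac muscle, 57.9 (Erg) for endothelial cells, 133 (Cd68) for blood and 1.28 (Nanog) for pluripotency. The share of 18S ribosomal RNA in the counts ranged from 0.0451 to 5.22% between libraries of the eGFP+ group, from 0.109 to 2.59% in tdTomato+ DMSO and from 0.185 to 4.62% in Fsk libraries.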
